A study of Mus musculus with 10 samples.

How the data were processed

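RNA from 10 mouse hearts, 5 treated with LPS and artesunate and 5 with LPS and vehicle, had been reverse transcribed after oligo-dT selection and sequenced in pairs, per the labels' protocols, which name NovaSeq and MGISEQ instruments without saying which sample ran on which. Groups and replicate numbers were taken from the treatment labels and sample titles, and all 10 columns of the table carried a sample title as name. The genome build named in the submitters' processing notes is mm9. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. A header that names only the samples gives no unit. The values deposited by the authors are FPKM, fragments or reads per kilobase of gene, per size of the library, as judged from the values. They had not been rescaled between samples: a library's values summed to 427020 ± 11557 in LPS+ART and 382668 ± 7627 in LPS+Vehicle (SD, n = 5 each).

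The table held 30074 Ensembl gene identifiers. Of these, 29538 (98.2%) were found in GENCODE M21, and 536 had no symbol. M21 belongs to a later build than mm9, yet 29005 of the matched genes (98.2%) gave whole reads with their M21 exon length, so no coordinates are printed. Each value was a whole multiple of what 1 read is worth in that gene and library. Read numbers were recovered for 30074 genes, with a length search for 1069 of them and a tolerance of 0.01 read. The library totals were 36463136, 31271119, 30684056, 33272861 and 36679402 reads in LPS+ART replicates 1 to 5. They were 30785586, 34097802, 54222272, 29980900 and 33285030 in LPS+Vehicle replicates 1 to 5. Of the read numbers of 1 to 4, 63.1% were even, as happens when the mates of a pair are counted apart, so reads are not independent. In a gene of 1 kb, 3 reads correspond to 0.0553 to 0.1001 FPKM, which covers counting error only. In simulated values the recovery gave 10 of 10 library totals exactly and 99.991% of the read numbers.

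The design fixed before the data were examined assumed counts. The deposited unit was FPKM, so the fallback written there was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) of genes with a mean of at least 0.5 FPKM, group as the only term, all 10 libraries and no scaling between samples. Calls are Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; fold values in words are ratios of mean FPKM. Count models such as edgeR and DESeq2 were not used. The fit keeps LPS+Vehicle replicates 2 and 5, which are nearly alike, as separate libraries. The labels do not state that replicates are separate animals beyond the group sizes of the design, and the p-values measure the spread between these libraries. On simulated data with 200 changed genes, limma called 4.1% of genes changed 1.25-fold, 29.2% at 1.5-fold, 96% at 2-fold and 100% at 4-fold among 13284 genes, with 12 unchanged genes called.

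The 43 gene lists, of pathways and of cell types a heart can hold, were fixed before the data were examined. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the 43 lists. In brackets that also follow a count after scaling, the p is that of the values as deposited. Members were counted at adjusted p under 0.05 over all genes tested. The count adjusted over the list alone was the same unless given. Named genes follow a rule fixed at the same time: the 12 largest rises and 12 largest falls among called genes with at least 5 FPKM in the higher group, without predicted genes, pseudogenes and immune receptor segments; up to 2 rises and 2 falls of each list; and 21 genes of the heart's stress, inflammatory and redox response. Some genes that the rule names are not reported here. The alternatives tried were median-ratio and TMM scaling, removal of the trend with expression level by cyclic loess, other library totals, pseudocounts of 0.1 and 0.5, no filter and a filter at 1, fold minimums, unadjusted p, the replicate number as a block, limma-voom on recovered reads, the 2 near-identical vehicle libraries averaged, LPS+ART replicates 3 and 4 left out, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.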

Results

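Gene expression was measured by RNA sequencing in whole hearts of C57BL/6 male mice, 8 to 12 weeks old and about 25 g, given lipopolysaccharide (LPS), the endotoxin of Gram-negative bacteria, to produce septic cardiomyopathy. In 5 mice artesunate, an endoperoxide antimalarial drug, was injected intraperitoneally at 50 mg/kg 10 min before LPS and again 4 h after it (LPS+ART). The other 5 mice received vehicle (LPS+Vehicle). The design places the assessment of cardiac function 24 h after LPS, and the time at which the hearts were taken for RNA was not given separately. Untreated and artesunate-only hearts were not analysed here, so the values carry no unstimulated baseline. The reads assigned to genes, as recovered from the values, numbered 30684056 to 36679402 per library in LPS+ART and 29980900 to 54222272 in LPS+Vehicle.

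The comparison of LPS+ART with LPS+Vehicle asks how the heart transcriptome under LPS differed when artesunate was given. Among the genes higher in LPS+ART than in LPS+Vehicle hearts were Nppb (B-type natriuretic peptide, 2019 ± 880 against 139 ± 53.2 FPKM, SD, n = 5 each) and Il6 (interleukin 6, 20.7 ± 10.9 against 0.958 ± 0.484 FPKM). Among the lower genes were Plin5 (a lipid droplet protein, 13.5 ± 2.57 against 109 ± 12.1 FPKM) and Cd163 (a scavenger receptor of resident macrophages, 1.06 ± 0.664 against 9.13 ± 2.29 FPKM). Of 13314 genes tested, limma called 1565 higher and 7037 lower in LPS+ART, so that 18.2% of the calls were higher. After median-ratio scaling of the same values, 3975 genes were higher and 4034 lower, and 49.6% of the calls were higher.

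The difference between these splits came with a shift of all genes: the median log2 fold change was -0.27 before scaling and 0.02 after it. All 1565 genes called higher were also called higher after scaling. Of the 7037 called lower, 4034 stayed lower, 2929 were no longer called and 74 were called higher. From 1 FPKM upward the change also followed expression level. The median log2 fold change was -0.35 at 1 to 5 FPKM, -0.31 at 5 to 20, -0.14 at 20 to 100 and 0.13 above 100 FPKM. Above 100 FPKM, 241 of 313 genes were higher after scaling and 13 lower. At 0.5 to 1 FPKM the median was -0.19, but adding 1 to each FPKM understates the change of such low genes. With this level trend removed by cyclic loess, limma called 3856 genes higher and 3827 lower, and 15 of the 23 gene lists called by camera lost the call, as given beside each. That setting would also remove a real rise shared by abundant genes. Gene values below are as deposited, and list medians are given relative to the median of all genes unless called log2 fold changes. Mitochondrially encoded genes took 27.04 ± 2.09% of the reads in LPS+ART and 22.03 ± 1.08% in LPS+Vehicle (SD, n = 5 each).

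**Figure D1:**
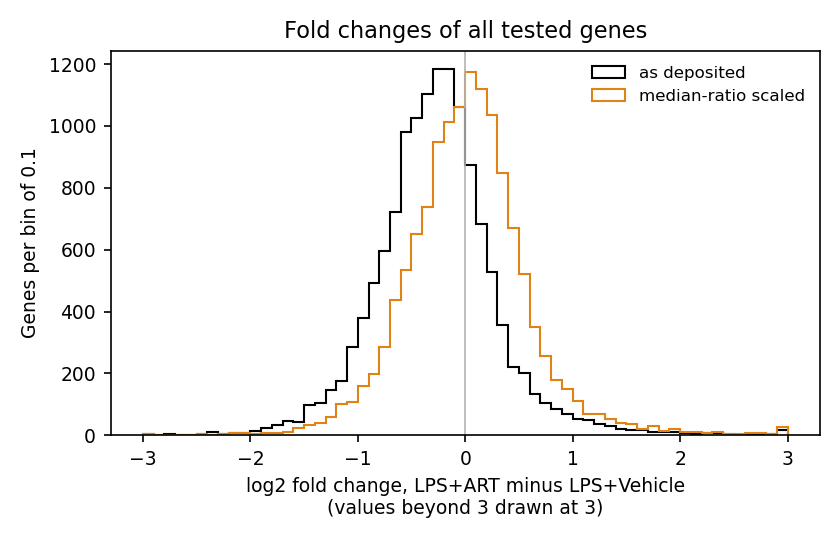
Number of tested genes (y axis, per bin of 0.1) by log2 fold change of LPS+ART minus LPS+Vehicle (x axis), for the values as deposited (black) and after median-ratio scaling (orange). The median lies at -0.27 as deposited and at 0.02 after scaling.

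The groups separated along the first principal component, which held 75.1% of the variance. The components were taken from the values as deposited, so the shift of all genes enters them as well. LPS+ART hearts lay between -50.6 and -24.5 and LPS+Vehicle hearts between 21 and 47.7. The second component split the LPS+ART hearts, with replicates 3 and 4 at -20.2 and -16.3 and replicates 1, 2 and 5 at 12.8 to 15.3. Cldn5, which encodes an endothelial tight junction protein, stood at 72.7 and 79.9 FPKM in replicates 3 and 4 and at 31.5 to 33.0 in the other LPS+ART hearts. With replicates 3 and 4 of LPS+ART left out, limma called 1527 genes higher and 6567 lower. What set them apart was not tested. In 6666 genes (50.1%) the 5 values of LPS+ART did not overlap those of LPS+Vehicle, against 0.79% by chance. LPS+Vehicle replicates 2 and 5 were nearly alike: their recovered reads, counted as pairs, differed with a chi-square per degree of freedom of 1.74 over 14533 genes, against 13.8 to 47.2 in every other pair within a group. With these 2 libraries averaged as 1 replicate, limma called 1430 genes higher and 6658 lower, of which 1412 and 6630 were among the calls above. Nothing in the labels says that they share an animal, and if they do, the vehicle SDs and the p-values would be too small.

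**Figure D2:**
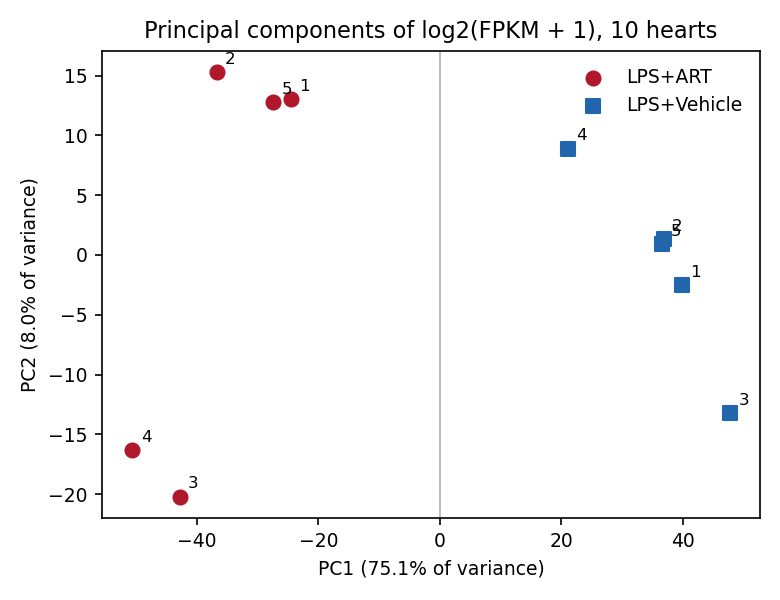
First and second principal components of log2(FPKM + 1) in the 10 hearts, with the share of variance on each axis; points are hearts, numbered by replicate, red circles LPS+ART and blue squares LPS+Vehicle. All 5 LPS+ART hearts lie below 0 on the first component and all 5 LPS+Vehicle hearts above it.

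The 12 largest rises included Ptx3, a soluble pattern recognition protein, at 113 ± 39.4 FPKM in LPS+ART against 6.58 ± 2.99 in LPS+Vehicle (log2 fold change 3.96, SE 0.33, limma adjusted p = 5.8e-06). Nppb, a marker of ventricular wall stress, rose by 3.83 (SE 0.38, limma adjusted p = 1.2e-05). Cd274, which encodes the immune checkpoint ligand PD-L1, stood at 497 ± 214 against 36.8 ± 15.2 FPKM. Ccn1, a matricellular protein, and Hbegf, a growth factor of the epidermal growth factor family, were 15.0-fold and 12.0-fold higher by mean FPKM. Otud1, a deubiquitinase, was 20.2-fold higher, Il6 21.6-fold and Csf3, which encodes granulocyte colony-stimulating factor, 9.24-fold. Cxcl10 stood at 73.1 ± 51.2 against 5.39 ± 0.697 FPKM and Cxcl5 at 114 ± 30.6 against 14.2 ± 9.28. Sphk1, a sphingosine kinase, stood at 31.3 ± 5.75 against 3.09 ± 1.75 FPKM.

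The 12 largest falls were led by Asb2, a subunit of a muscle ubiquitin ligase, at 5.04 ± 1.99 FPKM in LPS+ART against 65.0 ± 25.2 in LPS+Vehicle (log2 fold change -3.42, SE 0.28, limma adjusted p = 6.0e-06). Scd4, a cardiac stearoyl-CoA desaturase, fell from a mean of 12.9 to 0.437 FPKM, and Htra3, a secreted serine protease, from 19.2 to 1.13. Plin5 was 8.03-fold lower and Idh1, the cytosolic isocitrate dehydrogenase, 8.12-fold lower. Plin5 had the smallest adjusted p of the named genes (limma adjusted p = 8.2e-07). Sox18, an endothelial transcription factor, stood at 4.65 ± 3.16 against 27.6 ± 1.86 FPKM. Inpp5j, Phyhip, Tmem94 and Slc26a10 were 17.9-fold, 18.1-fold, 10.7-fold and 41.4-fold lower. Zfp970, a zinc finger gene of a large family with near-identical copies, stood at 19.3 ± 9.06 against 116 ± 15.7 FPKM, and its reads may be shared within the family. Reads at Mir133a-1, a microRNA precursor gene 18.6-fold lower (a mean of 0.459 FPKM in LPS+ART, and 0.221 without replicate 2), cannot be told from its host transcript. The genes named here among the largest rises and falls stayed called in the same direction after median-ratio scaling.

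**Figure D3:**
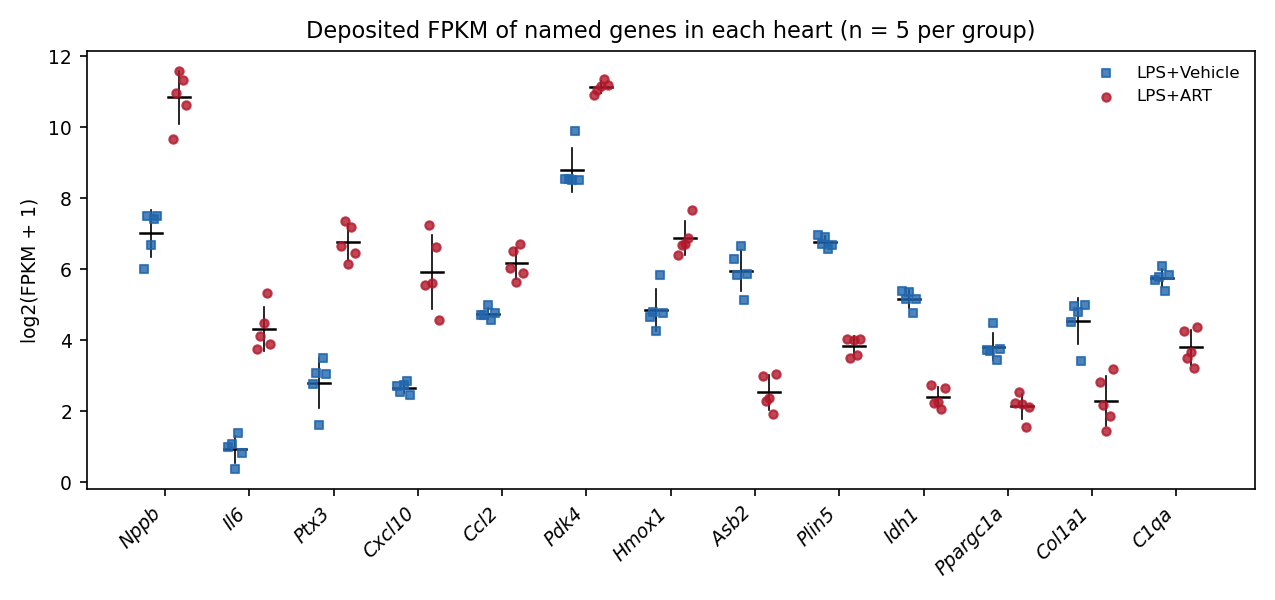
log2(FPKM + 1) of 13 named genes in each heart (n = 5 per group); red circles are LPS+ART, blue squares LPS+Vehicle, horizontal lines the mean and vertical lines the SD of the log values. In each of the 13 genes the values of the groups do not overlap, with the first 7 genes higher and the last 6 lower in LPS+ART.

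Inflammatory cytokines and NF-kB targets rose as a list: of 34 measured members 21 were higher and 3 lower, and the list median lay 0.74 above that of all genes (camera adjusted p = 4.3e-12, and adjusted p = 0.0192 with an estimated correlation). Il6, Csf3 and Ptgs2, the inducible cyclooxygenase (6.53 ± 2.84 against 1.32 ± 0.596 FPKM), rose, while Nfkbie, an inhibitor of NF-kB, and Il1a fell by 0.61 and 0.46 on the log2 scale. The list's best known cytokines did not follow: Il1b stood at 1.17 ± 0.624 against 1.33 ± 0.506 FPKM (limma adjusted p = 0.601) and Tnf at 1.73 ± 0.336 against 1.49 ± 0.533 (limma adjusted p = 0.395). Nos2, the inducible nitric oxide synthase, stood at 6.58 ± 4.70 against 2.39 ± 0.252 FPKM (limma adjusted p = 0.06). After median-ratio scaling Tnf and Nos2 passed the threshold, at adjusted p = 0.0366 and 0.0183 in limma, and Nos2 also did without LPS+ART replicate 3 (limma adjusted p = 0.00586) or replicate 4 (limma adjusted p = 0.0289). Chemokines rose likewise, with 11 of 23 higher, 5 lower and a median 0.80 above all genes (camera adjusted p = 1.5e-06, and 0.0192 as adjusted p with an estimated correlation). Ccl2, which attracts monocytes, rose from a mean of 26.1 to 73.6 FPKM. Cxcl13 and Cxcl12, chemokines of lymphocyte homing, fell by 2.16 and 1.05 on the log2 scale.

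Immediate-early genes, transcribed within minutes of a stimulus and also during tissue handling, showed the highest list median, 1.63 above all genes, with 24 of 27 members higher and 1 lower (camera adjusted p = 5.0e-20, and adjusted p = 0.139 with an estimated correlation). Ccn1 led them, and Btg2, an antiproliferative gene, stood at 155 ± 41.4 against 19.8 ± 6.65 FPKM. The member called lower, Klf4, lost its call after median-ratio scaling (limma adjusted p = 0.0911). Acute-phase and innate secreted proteins had 9 of 24 higher and 4 lower, with a median 0.48 above all genes (camera adjusted p = 7.0e-05, adjusted p = 0.31 with an estimated correlation and 0.108 with the level trend removed). Ptx3 and Serpina3f rose and Serpina3n fell, while Lcn2, which encodes lipocalin 2, stood at 797 ± 182 against 868 ± 93.7 FPKM (limma adjusted p = 0.426). Of 29 pattern recognition and inflammasome genes 6 were higher and 12 lower, but 15 higher and 5 lower after scaling. The list was called as deposited (camera adjusted p = 0.0298 upward, adjusted p = 0.31 with an estimated correlation and 0.0957 with the level trend removed). Its median log2 fold change was -0.04 and its mean -0.08, while the median lay 0.23 above all genes, the direction tested. The call was lost after scaling (camera adjusted p = 0.133). Tbk1 and Irak3 rose by 0.71 and 0.69, and Ticam1, an adaptor of Toll-like receptors, fell by 1.00.

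Guanylate-binding proteins and interferon-gamma-inducible GTPases had 16 of 22 members higher and 0 lower, with a median 1.32 above all genes (camera adjusted p = 1.6e-14, and adjusted p = 0.199 with an estimated correlation). Iigp1 stood at 433 ± 170 against 92.4 ± 43.1 FPKM, though these gene families hold near-identical copies among which reads could be shared. The list also holds genes of neither family, such as Irf1 and Cd274, and Cd274 was its largest rise (log2 fold change 3.73). Interferon-stimulated genes divided, with 18 of 50 higher and 9 lower (8 lower adjusted over the list alone), and 31 higher and 2 lower after median-ratio scaling (camera adjusted p = 6.1e-07, and adjusted p = 0.485 with an estimated correlation). Rsad2, an antiviral effector, and Mx2, annotated as a polymorphic pseudogene, were 3.8-fold and 2.98-fold higher, and Ifi27l2a was 3.41-fold lower. Of 24 antigen presentation genes 4 were higher and 1 lower, or 3 and 1 adjusted over the list alone, and after scaling 10 and 0 (camera adjusted p = 0.00453, adjusted p = 0.579 with an estimated correlation and 0.198 with the level trend removed). Their median log2 fold change was -0.02 and their mean 0.10. Nlrc5, the regulator of MHC class I genes, and the peptide transporter gene Tap1 rose by 1.39 and 1.21.

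Cardiac stress and fetal genes had 11 of 20 members higher and 5 lower, and 12 higher and 0 lower after scaling (camera adjusted p = 1.1e-06, and adjusted p = 0.18 with an estimated correlation). Nppb and Ccn1 led the rises. Nppa, the atrial natriuretic peptide gene, stood at 71.4 ± 52.4 against 108 ± 59.9 FPKM (limma adjusted p = 0.231), and was called lower with the replicate number as a block (limma adjusted p = 0.0495). Myh7, the fetal myosin heavy chain, fell by 0.75 on the log2 scale, and the call was lost after scaling (limma adjusted p = 0.107) and with the level trend removed (limma adjusted p = 0.051). Myh6, the adult myosin heavy chain, stood at 2302 ± 261 against 2374 ± 128 FPKM (limma adjusted p = 0.632), and Atp2a2, the sarcoplasmic calcium pump SERCA2, at 1535 ± 312 against 1496 ± 130 (limma adjusted p = 0.904). Relative to the other genes, by median-ratio scaling, both were called higher, with log2 fold changes of 0.34 and 0.41, but with the level trend removed Myh6 was called lower, by 0.33 (limma adjusted p = 0.00631), and Atp2a2 was not called (limma adjusted p = 0.154).

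Sarcomere genes had 13 of 29 higher and 6 lower, or 14 and 6 adjusted over the list alone, and 19 and 3 after scaling (camera adjusted p = 2.5e-04, adjusted p = 0.0801 with an estimated correlation and 0.923 with the level trend removed). Synpo2l and cardiac actin Actc1 were 3.66-fold and 2.22-fold higher, and the Z-disc genes Ldb3 and Nebl 3.18-fold and 1.95-fold lower. Cardiomyocyte markers had 10 of 16 higher and 4 lower (camera adjusted p = 2.5e-04, adjusted p = 0.139 with an estimated correlation and 0.828 with the level trend removed), with Myl2 up and the phospholamban gene Pln and the transcription factor gene Nkx2-5 down. Calcium handling and ion channel genes had 6 of 43 higher and 23 lower, and 9 higher and 19 lower after scaling, and the list was not called (camera adjusted p = 0.68). Kcnj5 and Kcnj11, which encode inwardly rectifying potassium channels, fell from means of 13.9 to 1.86 and of 23 to 4.31 FPKM, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose by 0.79. Of 11 atrial markers 0 were higher and 3 lower (camera adjusted p = 0.727), including Kcnj3. Of 22 genes of ubiquitin ligases and muscle atrophy 5 were higher and 11 lower, and 8 and 7 after scaling (camera adjusted p = 0.598). The atrophy ligases diverged, as Trim63 was 1.57-fold higher and Fbxo32 4.05-fold lower, and the cell cycle inhibitor gene Cdkn1a was 2.37-fold higher.

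Of 77 nuclear-encoded oxidative phosphorylation genes 30 were higher and 1 lower, or 17 and 1 adjusted over the list alone, and 75 higher and 1 lower after scaling, with a median 0.44 above all genes (camera adjusted p = 1.6e-16, adjusted p = 0.234 with an estimated correlation and 2.6e-04 with the level trend removed, where the median was 0.17). Abundant genes in general were higher after scaling. Ndufa5 and Cox8b were each 1.39-fold higher, and the exception was Cox6a1, 1.68-fold lower. Of the 13 mitochondrially encoded mRNAs 7 were higher and 0 lower, and 12 and 0 after scaling (camera adjusted p = 9.3e-07, adjusted p = 0.212 with an estimated correlation and 0.954 with the level trend removed). mt-Nd1 stood at 42160 ± 3808 against 25900 ± 2577 FPKM and mt-Nd2 at 22320 ± 2395 against 13640 ± 579. Cox8b and mt-Nd1 lost their calls with the level trend removed (limma adjusted p = 0.0704 and 0.0501). Regulators of mitochondrial dynamics and biogenesis had 4 of 32 higher and 23 lower, or 4 and 25 adjusted over the list alone, but 9 higher and 11 lower after scaling (camera adjusted p = 0.264). Ppargc1a and Ppargc1b, coactivators of mitochondrial biogenesis, were 3.88-fold and 3.31-fold lower and the deacetylase gene Sirt1 1.76-fold higher.

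Fatty acid uptake and oxidation genes had 3 of 43 higher and 18 lower, and 17 higher and 12 lower after scaling (camera adjusted p = 0.727). Pdk4, the kinase that restrains glucose oxidation, rose from 484 ± 260 to 2252 ± 266 FPKM and Angptl4, an inhibitor of lipoprotein lipase, from 16.8 ± 12.4 to 48.3 ± 18.9. Acot1, an acyl-CoA thioesterase, was 4.18-fold lower. Of 30 glycolysis and glucose uptake genes 9 were higher and 8 lower, and 18 and 4 after scaling (camera adjusted p = 0.00421, adjusted p = 0.371 with an estimated correlation and 0.588 with the level trend removed). Their median log2 fold change was 0.08 and their mean -0.02, with the median 0.35 above all genes. Hif1a and Pfkfb3 rose by 0.93 and 0.90, and Pfkfb2 and the lactate transporter gene Slc16a1 fell by 1.37 and 1.29. Of 36 genes of the TCA cycle and branched-chain amino acid breakdown 4 were higher and 7 lower, or 4 and 6 adjusted over the list alone, and 24 and 3 after scaling (camera adjusted p = 0.015, adjusted p = 0.732 with an estimated correlation and 0.566 with the level trend removed). Their median log2 fold change was 0.01 and their mean -0.10, with the median 0.28 above all genes. Acod1, which makes itaconate in activated macrophages, and Idh3a rose by 0.77 and 0.36. Autophagy and mitophagy genes had 3 of 38 higher and 21 lower, or 3 and 20 adjusted over the list alone, but 17 higher and 7 lower after scaling (camera adjusted p = 0.672). Gabarapl1 was 2.03-fold higher, and Tfeb, a regulator of lysosomal genes, and Atg5 were 3.98-fold and 2.25-fold lower.

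NRF2 targets and antioxidant enzymes had 4 of 38 higher and 15 lower, or 4 and 14 adjusted over the list alone, and 13 and 11 after scaling (camera adjusted p = 0.852). Hmox1, the inducible heme oxygenase, rose from 30.4 ± 15.1 to 122 ± 46.3 FPKM and Nfe2l2, which encodes NRF2, from 37.8 ± 8.78 to 58.7 ± 13.7, while Ephx1 and Aox1 were 3.91-fold and 3.19-fold lower. Of 34 ferroptosis and iron handling genes 11 were higher and 9 lower, and 16 and 5 after scaling (camera adjusted p = 0.0124, adjusted p = 0.31 with an estimated correlation and 0.237 with the level trend removed). Their median log2 fold change was -0.09 and their mean 0.14, with the median 0.18 above all genes. Hamp, the iron hormone hepcidin, and Sat1, a polyamine acetyltransferase, were 8.7-fold and 6.41-fold higher, and Aifm2, which encodes the ferroptosis suppressor FSP1, and Steap3 2.96-fold and 4.05-fold lower. Gpx4, the lipid peroxide reductase, stood at 123 ± 9.90 against 136 ± 4.67 FPKM (limma adjusted p = 0.0924, and 0.0466 and lower without LPS+ART replicate 1), and by median-ratio scaling it was called higher with a log2 fold change of 0.25 (limma adjusted p = 0.00567), which was lost with the level trend removed (limma adjusted p = 0.0822). Slc7a11, the cystine transporter gene, lay under the filter at a mean of 0.532 against 0.215 FPKM and was not tested. Of 18 genes of heme metabolism and xenobiotic response 4 were higher and 8 lower, or 4 and 9 adjusted over the list alone, and 7 and 4 after scaling (camera adjusted p = 0.727). The heme synthesis gene Cpox was 3.61-fold lower, and Tiparp, a target of the aryl hydrocarbon receptor, 3.14-fold higher.

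Unfolded protein and integrated stress response genes had 6 of 38 higher and 25 lower, and 10 higher and 16 lower after scaling (camera adjusted p = 0.5). The stress cytokine gene Gdf15 stood at 19.2 ± 17.1 against 2.93 ± 3.18 FPKM, where 1 library in each group weighed most: the means were 11.6 without LPS+ART replicate 5 and 1.52 without LPS+Vehicle replicate 4. Ppp1r15a, a phosphatase subunit that restores translation, was 3.35-fold higher, while the chaperone genes Pdia4 and Sdf2l1 were 3.98-fold and 3.21-fold lower. Heat shock proteins had 6 of 22 higher and 4 lower, and 13 and 2 after scaling (camera adjusted p = 0.0259, adjusted p = 0.521 with an estimated correlation and 0.669 with the level trend removed). Their median log2 fold change was -0.06 and their mean 0.04, with the median 0.21 above all genes. Without LPS+ART replicate 3 the list missed the threshold (camera adjusted p = 0.0507). Hspa8 and Hspb1 were 1.85-fold and 1.89-fold higher. Of 32 apoptosis and necroptosis genes 6 were higher and 10 lower, or 5 and 10 adjusted over the list alone, and 17 higher and 6 lower after scaling. The list was called as deposited (camera adjusted p = 0.0356, adjusted p = 0.485 with an estimated correlation and 0.133 with the level trend removed) but not after scaling (camera adjusted p = 0.148). Their median log2 fold change was 0.02 and their mean -0.10, with the median 0.29 above all genes. Bad and Fadd were 2.57-fold and 3.23-fold lower.

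Of 20 fibroblast markers 0 were higher and 13 lower, or 0 and 15 adjusted over the list alone, with a median -0.60 relative to all genes (camera adjusted p = 0.051, and adjusted p = 0.793 with an estimated correlation). The list passed after scaling (camera adjusted p = 0.0126), with the level trend removed (camera adjusted p = 0.0037), with the replicate number as a block (camera adjusted p = 0.0358) and without any of LPS+ART replicates 3, 4 and 5 or LPS+Vehicle replicates 1 and 4, at adjusted p = 0.0117 to 0.0424 in camera. Htra3 and Abca8a, a lipid transporter gene, were 17-fold and 14.8-fold lower. Smooth muscle and pericyte markers had 0 of 14 higher and 12 lower, with a median -0.53 relative to all genes (camera adjusted p = 0.0301, and adjusted p = 0.579 with an estimated correlation), led by Ndufa4l2 and Higd1b, 4.12-fold and 3.74-fold lower; without LPS+ART replicate 1 the list missed the threshold (camera adjusted p = 0.051). Extracellular matrix and fibrosis genes had 4 of 37 higher and 21 lower, or 4 and 22 adjusted over the list alone, and 10 and 16 after scaling (camera adjusted p = 0.991). The collagen genes Col1a1 and Col3a1 fell from means of 23.9 to 4.40 and of 39.8 to 9.03 FPKM, whereas the secreted protease gene Adamts1 and thrombospondin gene Thbs1 were 6.5-fold and 4.08-fold higher.

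Endothelial markers had 2 of 20 higher and 13 lower, and 6 higher and 8 lower after scaling (camera adjusted p = 0.727). Cldn5, a tight junction protein, rose from 11.2 ± 1.92 to 49.9 ± 24.2 FPKM, and Tek, the angiopoietin receptor, fell from 15.0 ± 2.85 to 4.19 ± 0.606. Of 23 genes of endothelial activation and adhesion 4 were higher and 9 lower, and 8 and 6 after scaling (camera adjusted p = 0.424). Selp, which encodes P-selectin, and the venular chemokine receptor gene Ackr1 were 2.08-fold and 2.4-fold higher, and Cd34 was 2.71-fold lower. Complement and coagulation genes had 5 of 25 higher and 13 lower, and 7 and 7 after scaling (camera adjusted p = 0.471). Plaur, the urokinase receptor gene, rose, and the complement genes C1qa and C1qc were 3.95-fold and 2.98-fold lower.

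Monocyte and macrophage markers had 2 of 23 higher and 15 lower, or 3 and 15 adjusted over the list alone, and 6 higher and 10 lower after scaling (camera adjusted p = 0.68). Cd163 and C1qa led the falls, and the monocyte marker Ly6c2 was 1.82-fold higher at 1.48 ± 0.368 FPKM. Neutrophil markers had 2 of 16 higher and 3 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.0249 upward, adjusted p = 0.752 with an estimated correlation, 0.289 with the level trend removed and 0.388 without LPS+ART replicate 3), and the call was also lost after scaling (camera adjusted p = 0.394). Hdc and Ngp rose, the latter at 21.04 ± 22.28 against 4.26 ± 1.67 FPKM, whereas S100a8 stood at 24.7 ± 22.2 against 12.1 ± 4.28 (limma adjusted p = 0.329) and S100a9 at 60.9 ± 58.6 against 28.0 ± 8.28 (limma adjusted p = 0.29). Without LPS+ART replicate 3 the LPS+ART means of Ngp, S100a8 and S100a9 were 11.5, 16.1 and 37.1 FPKM. The call of Ngp was lost without LPS+ART replicate 4 (limma adjusted p = 0.0536) and without LPS+Vehicle replicate 3 (limma adjusted p = 0.0578). Only 3 of 29 lymphocyte and NK markers passed the filter, 0 higher and 1 lower, Gzma (camera adjusted p = 0.852). Of 10 erythroid and platelet markers 4 were higher and 2 lower, and 5 and 0 after scaling. The list was called as deposited (camera adjusted p = 0.0184, adjusted p = 0.521 with an estimated correlation and 0.134 with the level trend removed) but not after scaling (camera adjusted p = 0.157), with the globin gene Hbb-bs 2.04-fold higher. Of 7 adipocyte markers 0 were higher and 4 lower, Lipe among them (camera adjusted p = 0.672). Of 5 measured markers of lung, liver, skeletal muscle, thymus or mesothelium 2 were higher and 0 lower (camera adjusted p = 0.0259, adjusted p = 0.289 with an estimated correlation and 0.151 with the level trend removed), the mesothelial gene Wt1 and Ckm, which heart muscle also expresses. That call was lost after scaling (camera adjusted p = 0.148).

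**Figure D4:**
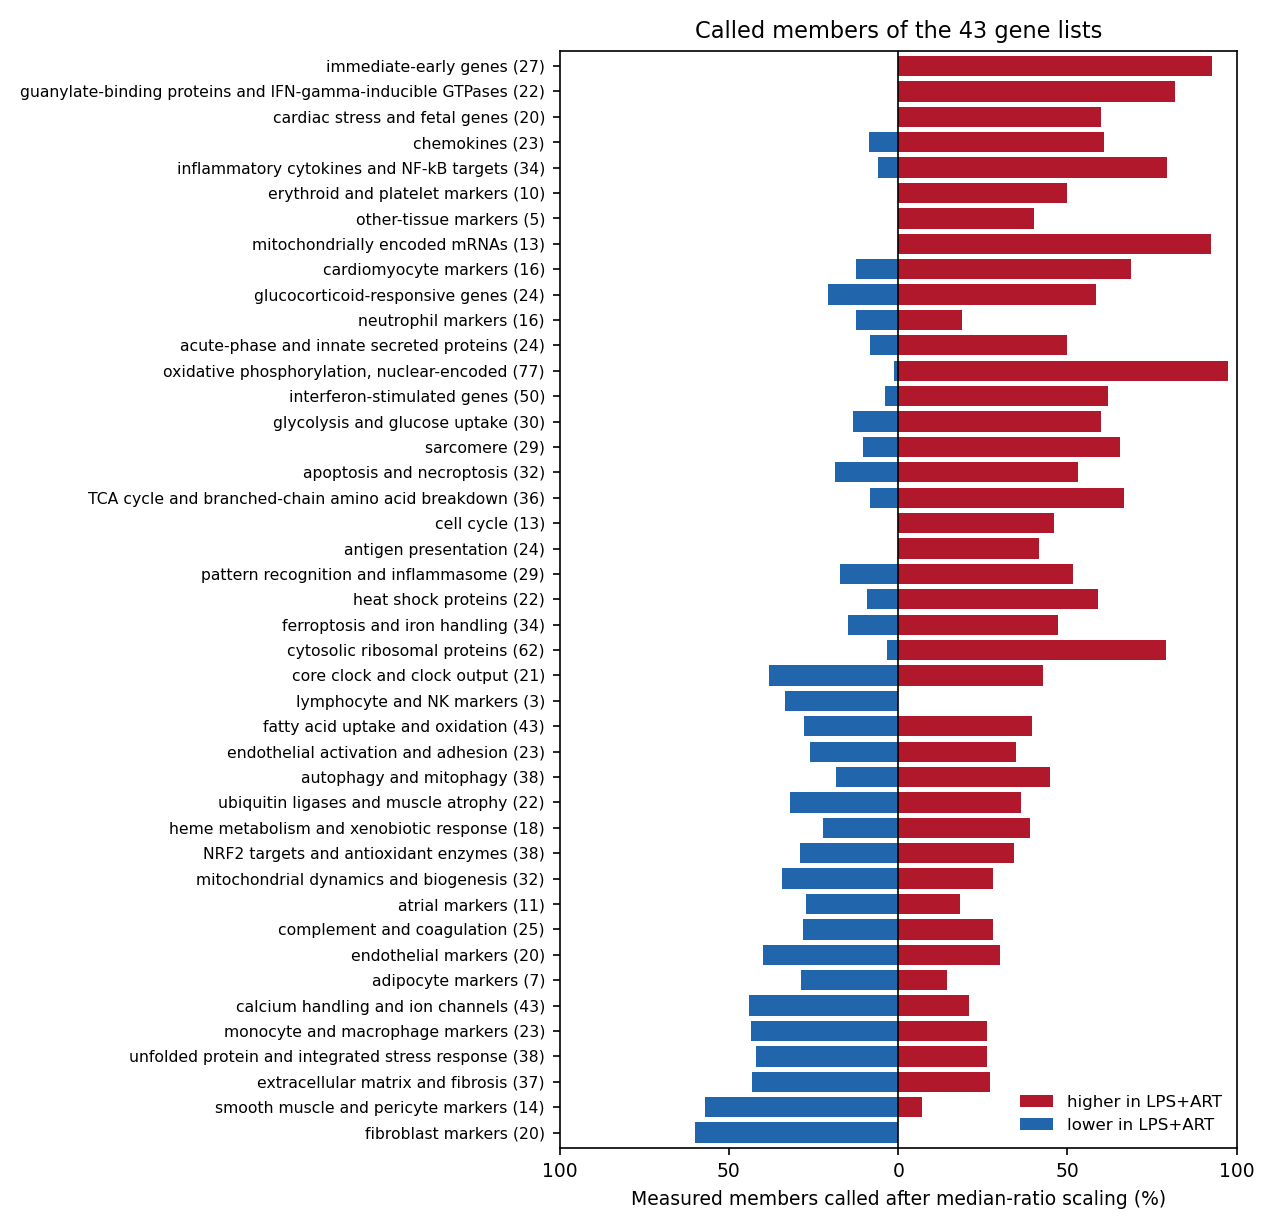
Percent of the measured members of each of 43 gene lists called higher (red, right) or lower (blue, left) in LPS+ART after median-ratio scaling, ordered by list median, with the number of measured members in parentheses. Immediate-early genes stand at the top with 25 of 27 members higher, and fibroblast markers at the bottom with 12 of 20 lower.

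The group comparisons rest on the labels, since no measured transcript marks exposure to artesunate independently. Of the 23 lists called by camera with its preset correlation, 2 kept the call with an estimated correlation, inflammatory cytokines and chemokines. With the level trend removed 8 kept it, among them the interferon-stimulated, nuclear-encoded oxidative phosphorylation and cardiac stress lists. The sarcomere, cardiomyocyte and mitochondrially encoded lists were not among the 8.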

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

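The tests of mitochondrial reads, gene length, macrophage markers, exchanged labels and repeated sequencing of 1 library were chosen after their results were seen. Of 290 groups of 5 values examined, 19 (6.6%) held a library set apart from the other 4 by a gap of over 0.71 of the range. The gap was taken on log2(FPKM + 1) for genes, and chance alone gives about 1 in 20 for 5 independent values. LPS+Vehicle replicate 3 was set apart in 10 results, LPS+Vehicle replicate 4 in 5, and LPS+ART replicates 1 and 5 in 2 each. Because LPS+Vehicle replicates 2 and 5 were nearly alike, the chance share does not hold for the vehicle groups, where a gap is reached more easily.

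LPS+Vehicle replicate 3 had the most reads assigned to genes among the vehicle libraries, 54222272 against 29980900 to 34097802. It stood apart in FPKM of Zfp970 (87.9 against 121 to 125), Cxcl13 (21.6 against 9.77 to 10.7), Serpina3f (3.19 against 6.94 to 7.32), Cdkn1a (30.9 against 46.8 to 50.3), Pfkfb3 (8.46 against 12.7 to 13.5), Gpx4 (144 against 133 to 135), Hspb1 (309 against 497 to 552), Selp (2.19 against 4.95 to 6.45) and Klf15 (22.4 against 17.3 to 18.1). LPS+Vehicle replicate 4, the vehicle heart nearest the treated ones, stood apart in Pdk4 (949 against 364 to 372), Angptl4 (39.0 against 9.99 to 12.5), Tfeb (3.35 against 4.08 to 4.35), Col3a1 (13.3 against 37.4 to 49.7) and Higd1b (4.41 against 7.56 to 9.21). LPS+ART replicate 1 was low in Sphk1 (21.5 against 31.9 to 35.6) and Sirt1 (4.80 against 7.93 to 9.63). LPS+ART replicate 5 was low in Hrc (218 against 285 to 311) and high in Gdf15 (49.6 against 9.27 to 14.3).

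Of 100 splits of the 10 libraries drawn from 126, the real split included, 1 gave as many genes higher as the 1565 observed. Likewise 1 gave as many lower as the 7037, in both cases the real split itself. The real split thus ranked first for both counts, but 100 splits cannot show a share below 1 in 100. The splits also took the nearly alike vehicle libraries as separate hearts, so chance was not excluded. The highest of the other splits had 0 genes called by limma and up to 6388 at an unadjusted p under 0.05. Those splits mix the groups, so the group difference widens their spread and lowers their calls. For the 23 lists called by camera, 5 of the 100 splits called as many, the highest other split calling 25. The other splits called a median of 16 lists. A camera call of a single list at the preset correlation thus also arose when the groups were partly mixed. Each other split still sets unequal numbers of LPS+ART and LPS+Vehicle libraries against each other, so part of the group difference remains in it. For the lists the splits therefore cannot tell chance from that difference, and chance was not excluded.

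More genes were lower than higher in LPS+ART as deposited. With mitochondrial reads left out of the totals the median log2 fold change of all genes was still -0.20, and with the 100 most abundant genes left out, which took 47% of reads in LPS+ART and 39% in LPS+Vehicle, it was -0.12. These values argue against either as the whole cause, although each moved the median from -0.27 toward 0. Protein-coding genes ranked into 5 equal sets by length had medians of -0.23 to -0.35, and the shortest set still had a median of -0.23, which argues against a loss of long transcripts as the whole cause. Each value is scaled to its library's total reads, so lower values in most genes go with a larger share for others. Genes above 100 FPKM had a median of 0.13, against -0.35 at 1 to 5 FPKM. Whether total RNA per heart differed was not measured.

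The inflammatory cytokine and immediate-early lists were called higher in LPS+ART, the latter not with an estimated correlation (camera adjusted p = 0.139). More monocytes and macrophages alike would raise most of their markers, but after median-ratio scaling 10 of the 23 measured ones were called lower and 6 higher, while the list as a whole was not called (camera adjusted p = 0.239; as deposited without a filter it was called lower, camera adjusted p = 0.033) and more monocytes with fewer resident macrophages stay open. An exchange of single labels would put libraries nearer to the other group's mean profile, and 0 of the 10 were. An exchange of whole groups cannot be told apart from right labels, since all 10 libraries lay nearer to their own labelled group and no transcript marks the drug. An effect of artesunate, a different stage of the LPS response and a difference in handling time between the groups stay open and untested. The instrument that sequenced each sample is not known, so a difference by instrument between the groups could not be tested either.

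LPS+Vehicle replicates 2 and 5 were nearly alike. A single library sequenced again would differ by sampling alone, with a chi-square per degree of freedom near 1, and over all genes it was 1.74. The excess lay in abundant genes, with a typical value of 1.07 to 1.12 at 20 to 3000 reads and 3.26 above 10000, so repeated sequencing with more noise in abundant genes stays open. Over the 500 genes that varied most among LPS+ART libraries, their median absolute log2 ratio was 0.101, against 0.293 to 0.389 in the other vehicle pairs. That is 0.343 of the smallest other pair, just over the bound set beforehand, so 1 RNA sample made into 2 libraries stays open.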

How the results depend on the processing

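The alternatives with TMM factors and with the 100 most abundant genes left out were chosen after seeing the data. TMM scaling was, however, part of the edgeR test planned for counts. Also chosen after seeing the data were LPS+Vehicle replicates 2 and 5 averaged, LPS+ART replicates 3 and 4 left out and the level trend removed. For gene lists and named genes, so were those on mitochondrial reads, pseudocounts, filters and quality weights. For gene lists, limma-voom with library totals was too. The 1565 genes higher and 7037 lower stayed within 1.5 times those counts under both pseudocounts, both filters, the replicate block (1533 and 6945), limma-voom with library totals (1574 and 7032) or quality weights (1703 and 7270), unadjusted p, mitochondrial reads left out (2004 and 6254), the averaged replicates (1430 and 6658) and LPS+ART replicates 3 and 4 left out (1527 and 6567). Leaving out 1 library gave 1401 to 1564 higher and 6530 to 7062 lower. Scaling between samples moved both counts by centring the fold changes near 0: 3975 and 4034 with median ratios, 3708 and 4231 with TMM, 3723 and 4281 with limma-voom and TMM, and 3856 and 3827 with the level trend removed. With the 100 most abundant genes left out, 2582 were higher, and 5388 lower. Fold minimums remove genes by construction, leaving 698 and 3325 at 1.5-fold and 307 and 1015 at 2-fold. The labels do not say that the replicate numbers pair the samples. The residuals of an LPS+ART library were closest to the vehicle library of its own number in 2 of 5 cases, too few to tell. Of 43 lists, 23 were called; 2 were with an estimated correlation, 28 with fry, 20 after median-ratio or TMM scaling, 10 with the level trend removed and 22 to 25 without 1 library. Median-ratio scaling ended the calls of pattern recognition, apoptosis, neutrophil, erythroid and other-tissue lists and added ribosomal proteins and fibroblast markers. Fibroblast markers also passed with the replicate block (camera adjusted p = 0.0358) and with LPS+ART replicates 3 and 4 left out (camera adjusted p = 0.0405), but not at a filter of 1 FPKM or with replicates 2 and 5 averaged. Removing the level trend ended 15 calls and added the cell cycle and fibroblast markers. Without a filter 7 lists lost and 6 gained the call, monocyte and macrophage markers among the latter (camera adjusted p = 0.033, lower). With fry 11 of the 23 lost the call, among them interferon-stimulated genes, antigen presentation, glycolysis, the TCA cycle and heat shock proteins. In fry, which tests the members' own direction and not that relative to other genes, 8 lists not called by camera were called opposite to its sign, with median log2 fold changes of -0.42 for complement, -0.21 for endothelial activation, -0.28 for NRF2 targets, -0.19 for fatty acid oxidation, -0.24 for ubiquitin ligases, -0.56 for extracellular matrix, -0.11 for the clock and -0.24 for heme metabolism. Of 168 named genes 158 were called, and 145 to 158 of these kept call and direction under each alternative. With the level trend removed Il1a, Cox8b, mt-Nd1, Myh7 and Gzma lost the call and Tnf and Nos2 gained it. Myh6 and Gpx4, not called as deposited, turned from negative to positive and were called after median-ratio scaling (0.34 and 0.25), TMM (0.31 and 0.22) and limma-voom with TMM (0.31 and 0.22). Nppa (limma adjusted p = 0.0495) and Nos2 (limma adjusted p = 0.0477) passed with the replicate block, Nos2 also with LPS+ART replicates 3 and 4 left out (limma adjusted p = 8.2e-05), and mt-Nd1 missed the threshold without a filter (limma adjusted p = 0.119). Fits with edgeR and DESeq2 and a surrogate variable from sva were not run. In simulated data with 200 changed genes, 29.2% of genes changed 1.5-fold were called. In the real data 64.6% of the genes tested were called, which makes the adjusted threshold less strict. The simulated share therefore does not carry over, and how many small changes were missed here is not known.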

Other observations

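Of 21 core clock and clock output genes 6 were higher and 8 lower, or 7 and 10 adjusted over the list alone, and 9 higher and 8 lower after scaling (camera adjusted p = 0.285). Ciart and Per1, repressors of the clock, were 2.82-fold and 1.82-fold higher, and Hlf, an output transcription factor, and Usp2 were 4.63-fold and 2.65-fold lower. Glucocorticoid-responsive genes had 11 of 24 higher and 8 lower, and 14 and 5 after scaling (camera adjusted p = 3.9e-04, adjusted p = 0.199 with an estimated correlation and 0.219 with the level trend removed). Members diverged, as Pdk4 and the metallothionein gene Mt2 were 4.65-fold and 6.54-fold higher while Klf15 and Tsc22d3, which encodes GILZ, were 2.64-fold and 2.07-fold lower.

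Cytosolic ribosomal protein genes had 5 of 62 higher and 13 lower, or 4 and 9 adjusted over the list alone, but 49 higher and 2 lower after median-ratio scaling (camera adjusted p = 0.098, adjusted p = 0.919 with an estimated correlation, and 8.5e-08 as adjusted p after scaling). Abundant genes in general rose after scaling, and with the level trend removed the list was not called (camera adjusted p = 0.588). The list also passed without LPS+ART replicate 3 (camera adjusted p = 0.0196) or LPS+Vehicle replicate 2 (camera adjusted p = 0.0343). Rps27 was 1.51-fold higher and Rpl3 1.81-fold lower. Of 13 measured cell cycle genes 2 were higher and 3 lower, or 2 and 2 adjusted over the list alone, and 6 and 0 after scaling (camera adjusted p = 0.0759, adjusted p = 0.521 with an estimated correlation, 0.0433 with the level trend removed and 0.0267 to 0.0404 without LPS+Vehicle replicate 1, 2, 3 or 5), with Mcm3 and Rrm2 higher at 2.74 ± 0.429 and 0.981 ± 0.274 FPKM.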
